A study of Mus musculus with 22 samples.

How the data were processed

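ATAC-seq libraries were made from immunoprecipitated liver nuclei of 22 male HEP-INTACT mice and sequenced in pairs of reads, per the labels' protocols. They fall into 6 groups: control, mild and advanced for the FPC diet (4, 4 and 3 libraries) and for the CDAHFD (4, 4 and 3). Replicate numbers only name libraries, and no paired analysis was possible because each library came from a different mouse. The labels name no sequencing batch, so none could be fitted.

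Per the submitters' processing notes, BWA 0.7.5a-r405, SAMtools, HOMER and DESeq2 were used with the mm10 build, and versions of the last 3 are not given in the sources used here. The deposited un-normalized table holds values per peak in steps of 0.5, which were taken for expected counts (47.8% of values carry a fraction of 0.5). The reason for the steps is not stated in the sources used here. The deposited normalized table holds a signal, which equals the counts cut to whole numbers and divided by 1 size factor per library. That was tested on the values: the ratio of the cut counts to the signal was constant within each library to 1.1e-14. Whether the factor is a median-ratio one was not tested. The authors' group means of this signal are in the same table and were not used. The distance of each peak to the nearest transcription start, the region type and the nearest gene are the authors' deposited annotation, per the file headers. Of neighbouring peaks, 3149 pairs overlap, so peaks are not fully independent. The peak with the lowest maximum still reached 31.5 counts in a library.

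Counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Libraries were scaled by TMM (factors 0.984 to 1.02), filterByExpr kept all 68827 peaks, and a quasi-likelihood model with the 6 groups and no intercept was fitted to all 22 libraries (common dispersion 0.0114). Contrasts compared advanced with control, mild with control and advanced with mild within each diet, the change from control between diets, the control groups, and the mean of both diets. A peak or gene was called at a Benjamini-Hochberg adjusted p under 0.05. SE values are the log2 fold change divided by the square root of the F statistic. Where a group held almost no counts they are not reliable standard errors and can be too small. For the Agfg1 peak in advanced livers they were 0.357 on FPC and 0.278 on CDAHFD, but 0.682 for the difference between diets. CPM values use the TMM-scaled totals, and log2 CPM a prior count of 2.

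For genes, counts were summed over all peaks whose nearest transcription start lay within 50 kb (56777 peaks, 82.5%), which gave 15686 genes, and were tested with the same model. A gene's sum measures open chromatin near it and not its expression. Of 26 gene lists with 451 genes, fixed before the data were examined together with the comparisons, tests and most alternatives, 382 genes had a peak. The lists cover hepatocyte transcription factors, secreted proteins and metabolism, bile acids, lipid and sterol synthesis, fatty acid oxidation, lipid droplets, xenobiotic metabolism, AP-1 and immediate early genes, biliary and progenitor genes, fibrosis factors, YAP and TEAD targets, inflammation, ER and integrated stress, NRF2 targets, p53 targets, cell cycle, pericentral and periportal zones, male-biased and female-biased genes, markers of stellate cells, macrophages, endothelium, lymphocytes and cholangiocytes, and a pair of transcription factors that the study chose. Lists with at least 3 measured genes (25) were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and with an estimated one, and with fry. Camera compares a list with all other genes, whereas fry tests whether its genes move, and neither says why.

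Named peaks were those with the largest change among called peaks with above-median abundance, no overlap between the libraries of both groups and a start within 50 kb, 1 per gene: 8 gained and 8 lost per diet for advanced against control, and 4 and 4 for the other comparisons. Named genes were up to 4 per list with the smallest p. Scd1, Fasn, Acaca, Pnpla3, Sqle, Hmgcs1, Alb, G0s2, Cd36, Plin4, Pparg, Hsd3b5, Ankrd1 and Krt19 were added after their values were seen. Promoter peaks are those within 1 kb of a transcription start, and unchanged peaks those with an unadjusted p above 0.5. The graded change is the mild change as a percent of the advanced change, taken over peaks called in advanced livers.

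The tests were run first on simulated data drawn from the real means and library sizes, for the comparison of advanced with control FPC. Of changed peaks among 68827, edgeR recovered 31.3% at 1.5-fold, 70.1% at 2-fold and 98.5% at 4-fold, with 4 false calls. Of changed genes among 15686 it recovered 73.1%, 92.5% and 100%, with 10 false calls. In this simulation 1.5-fold changes in single peaks were thus often missed. It changed only 66 or 67 peaks or genes per fold and did not vary depth. In the real comparison 55.6% of peaks passed, so these rates do not carry over to it. Camera gave a p of 1.26e-29 for a shifted set of 11 genes and p under 0.05 for 5 of 100 unchanged sets. The simulated genes were drawn independently, so these sets do not show how the preset correlation fares on correlated genes. In the real lists the estimated correlation was as high as 0.290 (female-biased genes).

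Alternatives were other scalings (RLE, total counts, cyclic loess with limma-voom), DESeq2 1.42.0, limma-trend on the deposited normalized signal, filters, thresholds, distances, sets of libraries, and leaving out each library in turn. Keeping the fractions of 0.5, cutting counts to whole numbers, thinning all libraries to the lowest total, and scaling promoter peaks apart were added after the data were seen. No mm10 sequence was at hand, so the planned search for 32 motifs and the GC correction were not run. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. A few results that meet the rules above are not reported here.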

Results

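Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts open chromatin, in liver nuclei of 22 male HEP-INTACT mice. In these mice hepatocyte nuclei carry a tag by which they were pulled out of the liver. Mice ate a FPC diet (rich in fructose, palmitate and cholesterol) for 20 weeks, or a CDAHFD (a choline-deficient, amino acid-defined, high-fat diet) for 7 weeks, and control mice ate a low fat diet for the same time. The submitters divided the mice on each diet by liver histology into a mild group and an advanced group. Both groups had steatosis and inflammation, and the advanced group alone had marked fibrosis. Each diet gave 4 control, 4 mild and 3 advanced libraries, each from a different mouse. Counts were given for 68827 peaks of 200 bp on mm10. The total count per library, in units of 1e6, ranged from 3.79 to 9.33. It averaged 4.50 ± 1.04 (SD, n = 4) in FPC controls, 5.58 ± 0.408 (n = 4) in mild FPC and 6.47 ± 0.601 (n = 3) in advanced FPC. In the CDAHFD arm it averaged 7.01 ± 1.02 (SD, n = 4), 7.66 ± 1.30 (n = 4) and 7.46 ± 1.62 (n = 3). The Pearson correlation of log2 CPM (counts per 1e6 counts), across peaks, lay between 0.925 and 0.969 for replicates of a group.

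Disease stage, not diet, separated most of the libraries. The first principal component held 62.1% of the variance, and both diets moved along it from control through mild to advanced. Its group mean was −119 ± 3.16 (SD, n = 4) in FPC controls, −1.62 ± 9.06 (n = 4) in mild FPC and 128 ± 24.8 (n = 3) in advanced FPC. In the CDAHFD arm the means were −127 ± 8.51 (SD, n = 4), 47.4 ± 11.8 (n = 4) and 139 ± 10.5 (n = 3).

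**Figure D1:**
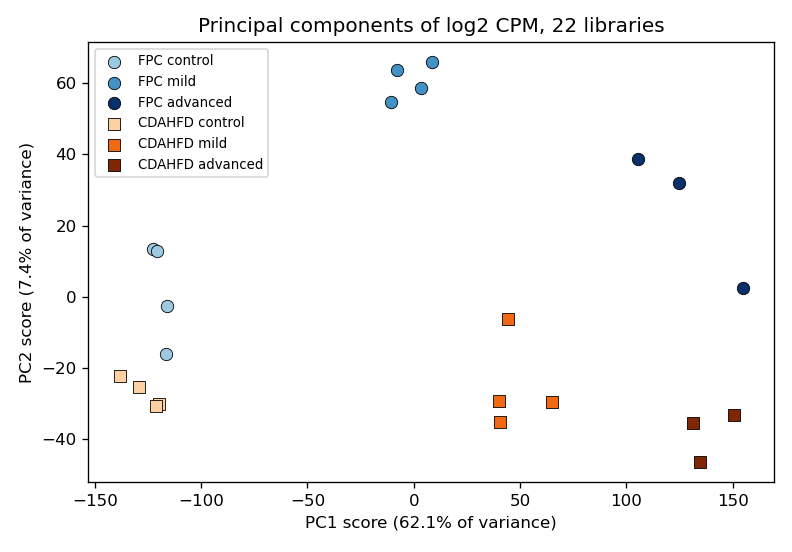
Scores of the 22 libraries on the first and second principal components of log2 CPM over 68827 peaks, 1 point per library, circles for the FPC arm and squares for the CDAHFD arm. Controls lie at the left (FPC mean −119), advanced livers at the right (FPC mean 128) and mild livers between them.

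The first comparison asks how hepatocyte chromatin in advanced, fibrotic disease on the FPC diet differs from that of controls. Genes of biliary and progenitor cells and target genes of YAP and TEAD, the Hippo pathway's effectors, gained accessibility, and genes of mature hepatocyte function lost it. Counts summed over the peaks of a gene rose for 16 of 17 measured biliary and progenitor genes and fell for 1. Cd24a, a surface glycoprotein of progenitor cells, rose by 3.56 ± 0.36 on the log2 scale (SE, n = 3 against 4), and Epcam, an epithelial adhesion molecule, by 2.72 ± 0.27. Of 15 measured male-biased genes 13 fell, among them Hsd3b5, a male-specific hydroxysteroid dehydrogenase, which fell by 2.03 ± 0.17. At the level of peaks, 18964 were higher and 19271 lower in edgeR, which is 55.6% of all peaks, and 7816 and 6655 of them changed more than 2-fold. At the level of genes, 4817 of 15686 rose (30.7%) and 4778 fell (30.5%).

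Among the biliary and progenitor genes, Bicc1, an RNA-binding protein of tubular epithelia, rose by 2.84 ± 0.24 and Sox4, a progenitor transcription factor, by 1.00 ± 0.09. The keratins Krt7 and Krt19 of bile duct cells rose by 2.88 ± 0.34 and 3.10 ± 0.39, from low levels. Krt7 stood at 1.00 CPM in controls and 7.92 CPM in advanced livers, and Krt19 at 1.19 and 9.83 CPM. Adjusted over the list alone the counts were also 16 and 1. The list passed camera (limma) with an adjusted p of 1.1e-05, and had adjusted p = 0.092 with an estimated correlation. Markers of cholangiocytes moved with it: 11 of 15 measured rose and 2 fell (camera adjusted p 0.0038, and adjusted p = 0.16 with an estimated correlation). Of those 15 markers, 11 are also members of other lists. Of 15 measured YAP and TEAD target genes 11 rose and 2 fell, also adjusted over the list alone (camera adjusted p 0.0014, and adjusted p = 0.10 with an estimated correlation). Ptpn14, a phosphatase that binds YAP, rose by 3.64 ± 0.31 and Myof, a membrane repair protein, by 2.96 ± 0.20. The single peak of Ankrd1, a muscle and stress protein, rose by 5.02 ± 0.55. Of 17 immediate early and AP-1 genes 13 rose and none fell, with 14 rising when adjusted over the list alone (camera adjusted p 0.00044, and adjusted p = 0.16 with an estimated correlation). The small Maf genes Mafk and Maff rose by 1.20 ± 0.08 and 1.16 ± 0.09, and Ier3, a stress response gene, by 1.58 ± 0.17. Of 25 measured genes of secreted factors that act in fibrosis, 12 rose and 7 fell (camera adjusted p 0.12). Pdgfb, a growth factor for stellate cells, rose by 3.79 ± 0.38 and Ctgf, a matrix regulator, by 1.39 ± 0.12.

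Genes of hepatocyte identity moved the other way. Of 18 hepatocyte transcription factor genes 14 fell and none rose (camera adjusted p 0.0037, and adjusted p = 0.16 with an estimated correlation). Their changes were small: Nr5a2, a nuclear receptor of bile acid and cholesterol metabolism, fell by 0.43 ± 0.05 and Thrb, a thyroid hormone receptor, by 0.31 ± 0.06. With cyclic loess scaling the call for this list ended (adjusted p = 0.13). Of 24 genes of secreted proteins and core metabolism 19 fell (camera adjusted p 6.6e-05, and adjusted p = 0.16 with an estimated correlation). Tdo2, which starts tryptophan breakdown, fell by 1.05 ± 0.11, Arg1, the last enzyme of the urea cycle, by 0.96 ± 0.12, and Serpinc1, the antithrombin gene, by 0.59 ± 0.07. Alb, the albumin gene, was −0.15 ± 0.08 and did not pass the test (adjusted p 0.11 in edgeR), but passed without FPC_Advanced replicate 1 (−0.21). Of 18 bile acid genes 13 fell, or 14 adjusted over the list alone (camera adjusted p 0.00017, and adjusted p = 0.16 with an estimated correlation). Slc10a1, the bile acid uptake transporter, fell by 1.06 ± 0.11, Slco1a1 by 1.11 ± 0.12 and Akr1d1, a bile acid synthesis reductase, by 0.92 ± 0.10. Of 18 xenobiotic genes 9 fell and none rose (camera adjusted p 0.015, and adjusted p = 0.39 with an estimated correlation). Of the male-biased genes 13 fell also when adjusted over the list alone (camera adjusted p 1.1e-05, and adjusted p = 0.092 with an estimated correlation). Susd4 fell by 2.46 ± 0.14 and Elovl3, a male-biased fatty acid elongase, by 1.31 ± 0.11. Female-biased genes went both ways, with 4 of 14 rising and 5 falling (camera adjusted p 0.85). Cyp2a4 rose by 1.33 ± 0.29 and Sult2a1 fell 2.83-fold.

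The other lists of this comparison held members of both directions. Of 22 measured lipid and sterol synthesis genes 3 rose and 11 fell (camera adjusted p 0.015, and adjusted p = 0.33 with an estimated correlation), a call that ended with cyclic loess scaling (adjusted p 0.21). Fatty acid oxidation gave 3 rising and 6 falling of 20 (camera adjusted p 0.43), with Fgf21, a fasting hormone, up by 0.91 ± 0.10 and Ppargc1a, a coactivator of oxidation genes, down by −0.93 ± 0.09. Lipid droplet genes gave 2 and 4 of 16 (camera adjusted p 0.85), with a median of 0.10, a mean of 0.00 and a downward camera direction. Inflammation and acute phase genes gave 9 and 7 of 25 (camera adjusted p 0.76), with a median of −0.00 against a mean of 0.08 and Icam1, an adhesion molecule, up by 0.65 ± 0.11. ER and integrated stress genes gave 4 and 3 of 15 (camera adjusted p 0.76), and NRF2 targets 5 and 5 of 16 (camera adjusted p 0.79). Among NRF2 targets the median was −0.02, the mean 0.03 and the camera direction down. For p53 targets the counts were 6 and 3 of 14 (camera adjusted p 0.63), with a median of −0.06 against a mean of 0.28. Cdkn1a, the p21 cell cycle inhibitor, rose by 1.69 ± 0.13 and Tnfrsf10b, a death receptor, by 2.12 ± 0.18. Cell cycle genes gave 9 and 3 of 17 (camera adjusted p 0.35), with Cdc20 up by 1.55 ± 0.16 and Ccnd2, a cyclin, up by 2.13 ± 0.25. Genes of the pericentral zone gave 2 and 8 of 18 (camera adjusted p 0.046, and adjusted p = 0.50 with an estimated correlation). That call also ended without FPC_Control replicate 2 (adjusted p 0.065), FPC_Control replicate 4 (0.055), FPC_Advanced replicate 2 (0.16) or FPC_Advanced replicate 3 (0.075). Periportal genes gave 4 and 10 of 17 (camera adjusted p 0.12), with Hal, which breaks down histidine, down by −0.86 ± 0.09 and Cdh1, the E-cadherin gene, up by 1.17 ± 0.10. In this comparison, counts adjusted over the list alone differed from the counts above by at most 1 gene per list and direction. The genes Elf3 and Glis2, which the study itself chose on such mice and which are therefore not independent evidence, rose by 0.43 ± 0.08 and 0.98 ± 0.07. With promoter peaks alone Elf3 was 0.16 and did not pass.

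Few markers of stellate cells, macrophages and lymphocytes had a peak. Of 21 stellate cell markers 4 were measured, and 2 rose and 1 fell (camera adjusted p 0.48). Of 22 macrophage markers 9 were measured, with 4 rising and 4 falling (camera adjusted p 0.85); their median was 0.08 and their mean −0.04. Of 20 endothelial markers 16 were measured, with 3 rising and 7 falling (camera adjusted p 0.38), and of 21 lymphocyte markers 3 were measured and 2 fell (camera adjusted p 0.12). Ptprc, the pan-leukocyte CD45 gene, fell by 0.94 ± 0.15 and Themis, a T cell gene, by 1.19 ± 0.09, while Col1a1, the collagen I gene, rose by 1.41 ± 0.16 from 12.7 to 34.0 CPM. In FPC controls Themis held 104 CPM and Ptprc 27.5 CPM, and whether this signal came from leukocytes was not tested. A fall in such sums, here or in later comparisons, therefore does not show fewer leukocytes. In 7 of the 35 ways to divide the 7 libraries into groups of 4 and 3, camera called at least as many lists as in the real division, and with an estimated correlation no list passed (7 of 25 had an unadjusted p under 0.05, and 18 passed limma's fry).

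**Figure D2:**
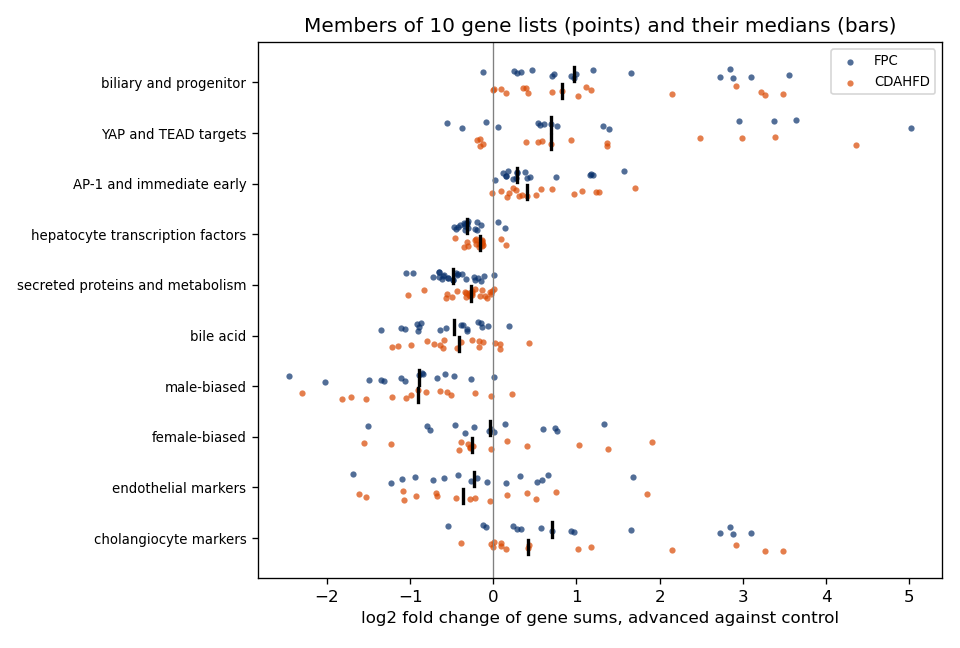
Log2 fold change of gene sums, advanced against control, for the members of 10 gene lists in the FPC (blue) and CDAHFD (orange) arms, 1 point per gene with the list median as a black bar. The biliary list has a median of 0.97 in FPC and 0.83 in CDAHFD, and the male-biased list −0.90 and −0.91.

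The 16 peaks named for this comparison include sites closed in controls and open in disease. The largest gain was a 200 bp intergenic peak 7429 bp upstream of Agfg1 (mm10 chromosome 1, 82831931 to 82832131), which rose by 6.46 ± 0.36 (adjusted p 3.5e-13, edgeR). It held 0.231 ± 0.317 CPM (SD, n = 4) in controls, 7.28 ± 1.66 CPM (n = 4) in mild and 26.3 ± 4.04 CPM (n = 3) in advanced livers. The FPC controls held 5 counts there in all, so the size and SE of its rise are imprecise. An intergenic peak 18646 bp upstream of Rasa2, a Ras GTPase activator (mm10 chromosome 9, 96650049 to 96650249), rose by 5.30 ± 0.28. A peak in intron 5 at Usp43 (mm10 chromosome 11, 67897035 to 67897235) rose by 5.18 ± 0.20, from 1.35 to 49.4 CPM. The other gained peaks, nearest to Kcnab1, Osbpl3, BC003331, Ppp2ca and Pgm1, rose by 4.88 to 5.64. The largest loss was an intronic peak 4560 bp from the start of Dkk4, a secreted Wnt antagonist (mm10 chromosome 8, 22628503 to 22628703). It fell by 4.59 ± 0.31 (adjusted p 8.4e-12, edgeR), from 19.2 ± 3.59 CPM (SD, n = 4) to 0.804 ± 0.483 CPM (n = 3). A peak in intron 1 of Prex1, a Rac activator (mm10 chromosome 2, 166676957 to 166677157), fell by 4.11 ± 0.30. The other lost peaks, nearest to 4930482G09Rik, Mcm5, Nfkbiz, Ttc36, Slc7a15 and Tmem50a, changed by −3.63 to −3.46. The nearest gene is a matter of distance alone, and no gene expression was used here.

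**Figure D3:**
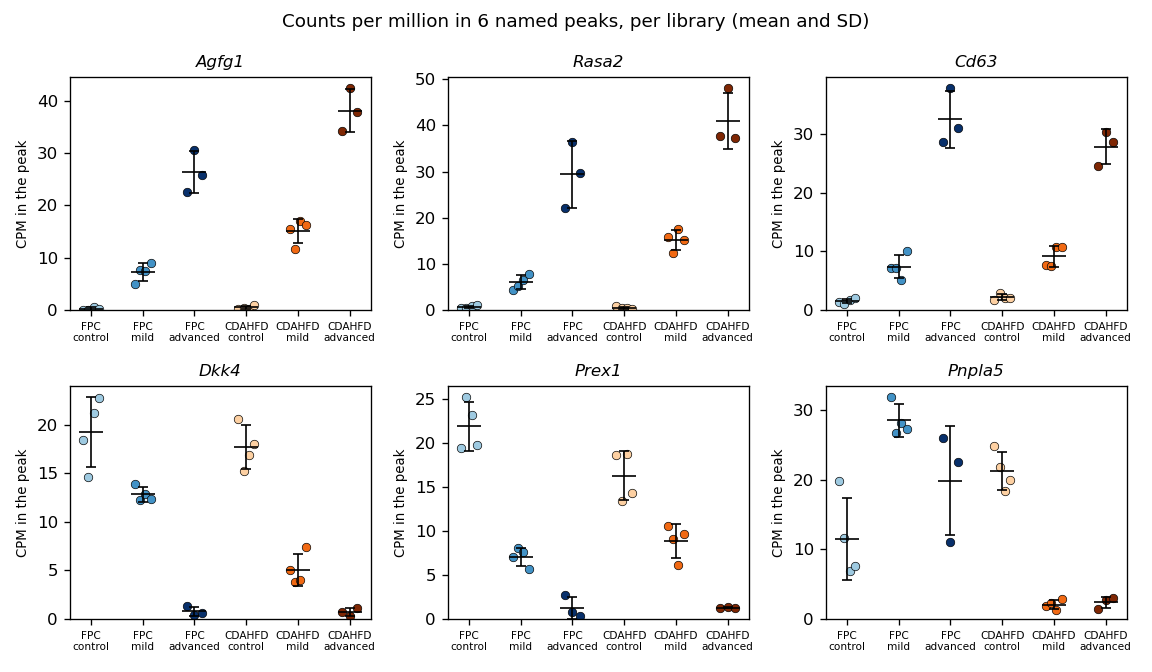
Counts per in 6 named peaks, 1 point per library, with the group mean and SD as bars and the 6 groups on the horizontal axis. The Agfg1 peak holds 0.231 CPM in FPC controls and 26.3 CPM in advanced FPC livers, and the Pnpla5 peak is low in mild and advanced CDAHFD livers alone (2.07 and 2.38 CPM).

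The second comparison asks the same of advanced disease on the CDAHFD. Most biliary, YAP and male-biased genes changed in the same direction as on FPC. Of 17 biliary and progenitor genes 13 rose and none fell, and of 15 YAP and TEAD targets 11 rose and 3 fell. Of 15 male-biased genes 12 fell. Cd24a rose by 3.21 ± 0.35 on the log2 scale (SE, n = 3 against 4), Epcam by 2.15 ± 0.26 and Ptpn14 by 3.39 ± 0.32. Hsd3b5 fell by 1.82 ± 0.16 and Susd4 by 2.30 ± 0.13. In edgeR 18382 peaks were higher and 19851 lower, 55.5% of all, of which 8326 and 6437 changed more than 2-fold, and 4466 genes rose (28.5%) and 4707 fell (30.0%).

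The biliary list had a camera adjusted p of 4.6e-05, and adjusted p = 0.10 with an estimated correlation. Krt7 and Krt19 rose by 3.27 ± 0.42 and 3.48 ± 0.43 and Bicc1 by 2.92 ± 0.25. Of the cholangiocyte markers 8 of 15 rose and 1 fell (camera adjusted p 0.020, and adjusted p = 0.27 with an estimated correlation). YAP and TEAD targets had a camera adjusted p of 0.0013, and adjusted p = 0.10 with an estimated correlation. Myof rose by 2.99 ± 0.19 and Ankrd1 by 4.36 ± 0.58. Of 17 AP-1 and immediate early genes 15 rose and none fell (camera adjusted p 4.6e-05, and adjusted p = 0.14 with an estimated correlation), with Ier3 up by 1.70 ± 0.15 and Maff by 1.27 ± 0.09. Of 25 fibrosis factor genes 13 rose and 5 fell, or 8 adjusted over the list alone (camera adjusted p 0.13). Pdgfb rose by 3.56 ± 0.41 and Tgfb1, the main profibrotic cytokine, by 1.22 ± 0.15. The male-biased list had a camera adjusted p of 4.6e-05, and adjusted p = 0.10 with an estimated correlation. Bile acid genes gave 1 rising, Abcc3, and 13 falling of 18, or 14 falling adjusted over the list alone (camera adjusted p 0.0039, and adjusted p = 0.27 with an estimated correlation). Slc10a1 fell by 1.15 ± 0.11. Secreted protein and metabolism genes gave 15 falling of 24 (camera adjusted p 0.0070, and adjusted p = 0.27 with an estimated correlation), with Arg1 down by −0.83 ± 0.12. Of 18 hepatocyte transcription factor genes 8 fell (camera adjusted p 0.053). That list passed without CDAHFD_Control replicate 4 (adjusted p 0.033), CDAHFD_Advanced replicate 2 (0.042) or CDAHFD_Advanced replicate 3 (0.038). Lipid and sterol synthesis genes gave 2 rising and 15 falling of 22 (camera adjusted p 0.022, and adjusted p = 0.27 with an estimated correlation), with Thrsp, a regulator of fatty acid synthesis, down by −1.67 ± 0.18. That call also ended with cyclic loess scaling (adjusted p 0.065).

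ER and integrated stress genes gave 10 rising and 3 falling of 15 (camera adjusted p 0.060), with Hspa5, the ER chaperone BiP, up by 0.70 ± 0.06. The list passed without CDAHFD_Control replicate 3 (adjusted p 0.047). NRF2 targets gave 7 and 2 of 16 (camera adjusted p 0.11), with Nqo1, an antioxidant reductase, up by 1.07 ± 0.10. For p53 targets the counts were 8 and 1 of 14 (camera adjusted p 0.028, and adjusted p = 0.23 with an estimated correlation), with Cdkn1a up by 1.60 ± 0.12 and Mdm2, which restrains p53, by 0.51 ± 0.07. Inflammation genes gave 13 and 4 of 25 (camera adjusted p 0.065), with Icam1 up by 0.86 ± 0.10 and Mlkl, a necroptosis gene, by 1.05 ± 0.15. This list passed without CDAHFD_Advanced replicate 1 (adjusted p 0.028). Cell cycle genes gave 8 and 4 of 17 (camera adjusted p 0.21), xenobiotic genes 3 and 10 of 18 (0.12) and fatty acid oxidation genes 3 and 6 of 20 (0.35). Lipid droplet genes gave 5 and 4 of 16 (camera adjusted p 0.73), with a median of −0.01 against a mean of 0.06. Pericentral genes gave 3 and 7 of 18 (camera adjusted p 0.64), with a median of 0.04 against a mean of −0.09, and periportal genes 4 and 7 of 17 (camera adjusted p 0.49). Female-biased genes gave 4 and 4 of 14 (camera adjusted p 0.84), with a median of −0.26 against a mean of 0.01, and Cyp2a4 up by 1.91 ± 0.26. Glis2 rose by 0.32 ± 0.07, and Elf3 was 0.13 ± 0.08 and did not pass. Endothelial markers gave 4 rising and 8 falling of 16 (camera adjusted p 0.15), with Tie1 down by −1.62 ± 0.15. Macrophage markers gave 2 and 4 of 9 (camera adjusted p 0.70), with a median of 0.05 against a mean of −0.03, stellate markers 2 and 1 of 4 (0.49) and lymphocyte markers 1 and 2 of 3 (0.14). Apart from the fibrosis factors, counts adjusted over the list alone differed by at most 1 gene per list and direction. Here too 7 of 35 divisions of the libraries gave at least as many lists in camera, and none passed with an estimated correlation (4 of 25 had an unadjusted p under 0.05, and 19 passed fry).

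The largest gain on the CDAHFD was a peak in intron 2 near Osbpl3, an oxysterol-binding protein gene (mm10 chromosome 6, 50390420 to 50390620), which rose by 6.89 ± 0.33 (adjusted p 9.2e-15, edgeR). The CDAHFD controls held 5 counts there in all, so the size and SE of its rise are imprecise too. The Rasa2 and Agfg1 peaks rose 79.0-fold and 78.6-fold. A peak 13209 bp from Mir181c (mm10 chromosome 8, 84192070 to 84192270) rose by 6.23 ± 0.27. The other gained peaks, nearest to Pgm1, 9130401M01Rik, BC003331 and Mir1953, rose by 5.45 to 6.02. The largest loss lay in an intron near Gm30332 (mm10 chromosome 6, 138455826 to 138456026), where accessibility fell by 4.55 ± 0.21. The Dkk4 peak fell by 4.51 ± 0.30, from 17.7 ± 2.26 CPM (SD, n = 4) to 0.740 ± 0.402 CPM (n = 3). A peak in intron 1 of Camk2b, a calcium-dependent kinase (mm10 chromosome 11, 6050233 to 6050433), fell by 4.17 ± 0.24. The others, nearest to Gm13547, Prex1, A930013F10Rik, Pard3b and Trhde, changed by −4.09 to −3.50.

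The 2 diets opened and closed largely the same peaks in advanced disease. Of the gained peaks 14254 were shared, which is 75.2% of those on FPC and 77.5% of those on CDAHFD, against 5065 expected by chance (odds ratio 33.6). Of the lost peaks 14801 were shared, against 5558 expected (odds ratio 29.2). Of the 29222 peaks called on both diets 167 went in opposite directions. Across peaks, which are not independent replicates, the log2 changes had a Pearson correlation of 0.912 and a Spearman correlation of 0.867. For the average of both diets 22517 peaks were higher and 24155 lower, led by Agfg1 with a rise of 6.38 ± 0.22 and Osbpl3 with 6.13 ± 0.23. On the losing side stood Dkk4 with −4.55 ± 0.21 and Gm30332 with −3.99 ± 0.14.

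**Figure D4:**
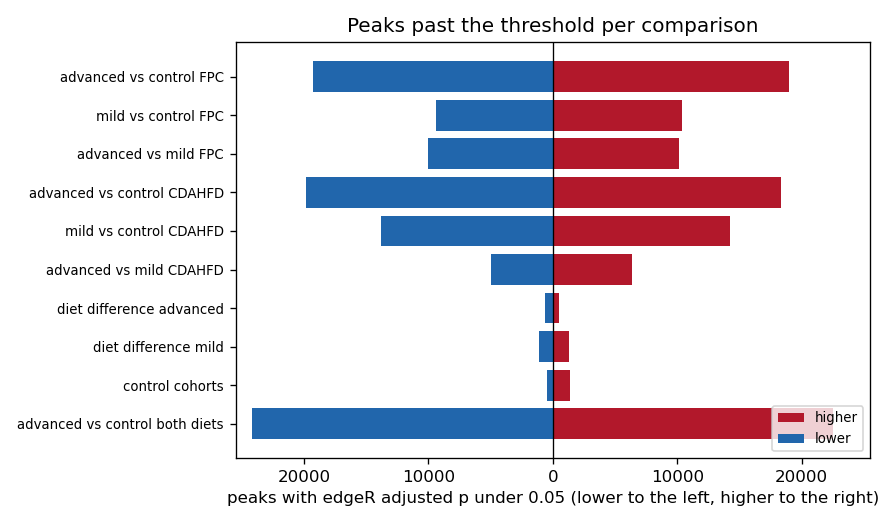
Number of peaks past an edgeR adjusted p of 0.05 in each comparison, lower to the left in blue and higher to the right in red. Advanced against control gives 18964 higher and 19271 lower peaks in FPC and 18382 and 19851 in CDAHFD, while the difference between diets gives 475 and 626 for the advanced groups.

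The next comparison asks what had changed in livers with steatosis and inflammation but little fibrosis. In mild FPC livers the same direction was seen for progenitor, YAP and male-biased genes, at smaller size. Cd24a rose by 1.73 ± 0.42 (SE, n = 4 against 4), Ptpn14 by 1.72 ± 0.36 and Myof by 1.58 ± 0.21. The p53 target Cdkn1a rose by 1.44 ± 0.13, and Hsd3b5 fell by 1.06 ± 0.14. Of 16 lipid droplet genes 9 rose and 2 fell, and the list did not pass (camera adjusted p 0.064, and adjusted p = 0.40 with an estimated correlation). Plin4, a lipid droplet coat protein, rose by 0.56 ± 0.11 and Cd36, a fatty acid transporter, by 0.55 ± 0.11. In edgeR 10403 peaks were higher and 9391 lower, which is 28.8% of all, and 3097 genes rose (19.7%) and 3232 fell (20.6%).

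In this comparison 10 of 17 biliary and progenitor genes rose and 1 fell (camera adjusted p 0.019, and adjusted p = 0.40 with an estimated correlation), 10 of 15 YAP and TEAD targets rose and 2 fell (camera adjusted p 0.020, and adjusted p = 0.40 with an estimated correlation), and 7 of 17 AP-1 genes rose (camera adjusted p 0.011, and adjusted p = 0.40 with an estimated correlation). Of 15 cholangiocyte markers 5 rose and 1 fell (camera adjusted p 0.29), of 16 endothelial markers 2 rose and 4 fell (0.30), of 9 macrophage markers 3 fell (0.93), of 4 stellate markers 1 rose and 1 fell (0.89) and of 3 lymphocyte markers 2 fell (0.44). Of the male-biased genes 7 of 15 fell, or 8 adjusted over the list alone (camera adjusted p 0.0042, and adjusted p = 0.40 with an estimated correlation). Elovl3 was −0.01 ± 0.09 and did not pass. Secreted protein genes gave 14 falling of 24, or 15 adjusted over the list alone (camera adjusted p 0.0024, and adjusted p = 0.40 with an estimated correlation), and bile acid genes 1 rising and 9 falling of 18 (camera adjusted p 0.039, and adjusted p = 0.50 with an estimated correlation). Periportal genes gave 2 and 9 of 17, or 2 and 10 adjusted over the list alone (camera adjusted p 0.019, and adjusted p = 0.40 with an estimated correlation). G0s2, which blocks lipolysis, rose by 0.51 ± 0.12 and Pparg, a regulator of lipid storage, by 0.34 ± 0.07, although promoter peaks alone gave 0.17 for G0s2, which did not pass, and −0.03 for Pparg. The 4 genes G0s2, Cd36, Plin4 and Pparg were singled out after their values were seen. The leading gained peaks were those of Agfg1 (4.62 ± 0.44), Kcnab1 (4.46 ± 0.40), Ppp2ca (4.33 ± 0.24) and BC003331 (4.32 ± 0.35). The leading loss was a promoter peak of Adgrf1, an adhesion receptor (mm10 chromosome 17, 43270293 to 43270493), which fell by 2.60 ± 0.33, from 43.6 ± 11.5 to 7.39 ± 3.34 CPM (SD, n = 4 each). Peaks nearest to Larp4b, Irf5 and Smim15 changed by −1.91, −1.87 and −1.84. Of the gained peaks 8947 and of the lost peaks 8157 were also called in advanced FPC livers, in the same direction, against 2866 and 2629 for independent lists. Both comparisons use the same controls, so part of the excess may come from them.

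The same was asked of mild CDAHFD livers. Of the biliary and progenitor genes 12 of 17 rose, of YAP and TEAD targets 10 of 15 rose and 1 fell, and of male-biased genes 11 of 15 fell. Cd24a rose by 2.08 ± 0.38 (SE, n = 4 against 4), Bicc1 by 1.37 ± 0.28 and Ptpn14 by 2.32 ± 0.33. Hsd3b5 fell by 1.31 ± 0.14, Cyp2d9, a male-specific cytochrome, by 1.00 ± 0.12 and Elovl3 by 0.75 ± 0.09. In edgeR 14219 peaks were higher and 13780 lower, which is 40.7% of all, and 3466 genes rose (22.1%) and 3655 fell (23.3%). Camera gave adjusted p values of 0.0045 for biliary, 0.00069 for YAP and TEAD and 0.00069 for male-biased genes, and with an estimated correlation adjusted p = 0.20, 0.12 and 0.20. Of 15 cholangiocyte markers 6 rose and none fell (camera adjusted p 0.13), with a median of 0.03 and a mean of 0.50. Of 16 endothelial markers 3 rose and 7 fell (camera adjusted p 0.092), of 9 macrophage markers 1 rose and 3 fell (0.47) and of 3 lymphocyte markers 1 rose and 2 fell (0.47). Of 4 stellate markers 1 rose (camera adjusted p 0.76), with a median of −0.04 against a mean of 0.19. Of 17 AP-1 genes 9 rose, or 11 adjusted over the list alone (camera adjusted p 0.00073, and adjusted p = 0.20 with an estimated correlation). Stress lists also passed, with 6 rising and 1 falling of 15 for ER and integrated stress, or 7 and 1 adjusted over the list alone (camera adjusted p 0.035, and adjusted p = 0.20 with an estimated correlation), 8 and 2 of 16 NRF2 targets, or 9 and 2 (camera adjusted p 0.038, and adjusted p = 0.24 with an estimated correlation), and 6 and 1 of 14 p53 targets (camera adjusted p 0.035, and adjusted p = 0.20 with an estimated correlation). Inflammation genes gave 11 and 3 of 25, or 13 and 3 adjusted over the list alone (camera adjusted p 0.035, and adjusted p = 0.26 with an estimated correlation). Secreted protein genes gave 11 falling of 24 (camera adjusted p 0.020, and adjusted p = 0.38 with an estimated correlation), bile acid genes 2 rising and 9 falling of 18, or 2 and 11 adjusted over the list alone (camera adjusted p 0.038, and adjusted p = 0.42 with an estimated correlation), and lipid and sterol synthesis genes 3 and 9 of 22 (camera adjusted p 0.042, and adjusted p = 0.40 with an estimated correlation). Of the lipid droplet genes 5 of 16 rose and 3 fell (camera adjusted p 0.49), with a median of −0.02 against a mean of 0.09. The leading gained peaks were those of Osbpl3 (5.64 ± 0.36), Agfg1 (4.97 ± 0.30), Rasa2 (4.87 ± 0.28) and Pgm1 (4.80 ± 0.26). The leading loss was a peak in intron 7 near Pnpla5, a lipid hydrolase gene (mm10 chromosome 15, 84115149 to 84115349), which fell by 3.30 ± 0.29 (adjusted p 1.6e-09, edgeR). It went from 21.3 ± 2.76 CPM in controls to 2.07 ± 0.663 CPM in mild livers (SD, n = 4 each). Peaks nearest to Pard3b, Dmbt1 and Sspo changed by −3.22, −2.97 and −2.68. Of the gained peaks 12971 and of the lost peaks 12113 were also called in advanced CDAHFD livers, against 3798 and 3974 for independent lists, and here too part of the excess may come from the shared controls. Between the diets 7206 gained and 5884 lost peaks of mild livers were shared, against 2149 and 1880 expected, and 181 of the 13271 called on both went in opposite directions. Across peaks the Pearson correlation was 0.768 and the Spearman correlation 0.683.

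Mild livers thus lay between control and advanced livers on both diets, and further along on CDAHFD. Over the peaks called in advanced livers, the change in mild livers had a median of 48.9% of the advanced change on FPC and 63.5% on CDAHFD. Single mild libraries gave 45.1% to 52.2% on FPC (mean 48.7% ± 3.55, SD, n = 4) and 59.1% to 70.9% on CDAHFD (mean 63.3% ± 5.24, n = 4). All 4 CDAHFD values lay above all 4 FPC values (two-sided exact permutation p 0.0286, the smallest that 4 against 4 allows). The 4 values of a diet share their advanced and control libraries, so this p covers only the spread between mild libraries. The mild and advanced changes share their controls, and with separate controls for each the medians were 46.3% to 50.7% and 59.9% to 65.9%. Across all peaks the mild and advanced changes had a correlation of 0.843 on FPC and 0.938 on CDAHFD, where 20 simulations of unchanged groups against the same controls gave means of 0.519 and 0.475. The covariance was 0.451 and 0.691, against 0.0241 and 0.0192 in the simulations. With the controls split in 6 ways the correlation was 0.7102 to 0.804 and 0.846 to 0.906. Diet, feeding time and cohort differ together here and cannot be separated.

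The comparison of advanced with mild livers asks what goes with fibrosis within a diet. On FPC most biliary, cholangiocyte and YAP genes were higher in advanced livers, and many genes of hepatocyte function were lower. Of 17 biliary and progenitor genes 13 rose and none fell, or 15 rose adjusted over the list alone (camera adjusted p 6.8e-08, and adjusted p = 0.051 with an estimated correlation). Of 15 cholangiocyte markers 10 rose and 1 fell (camera adjusted p 8.7e-05, and adjusted p = 0.074 with an estimated correlation), and of 15 YAP and TEAD targets 10 rose and 1 fell (camera adjusted p 0.00042, and adjusted p = 0.061 with an estimated correlation). Of 17 AP-1 genes 9 rose and none fell, or 10 adjusted over the list alone (camera adjusted p 0.0020, and adjusted p = 0.19 with an estimated correlation). Bile acid genes gave 11 falling of 18 (camera adjusted p 1.8e-05, and adjusted p = 0.13 with an estimated correlation) and hepatocyte transcription factors 10 of 18, or 11 adjusted over the list alone (camera adjusted p 0.0020, and adjusted p = 0.13 with an estimated correlation). Secreted protein genes gave 8 falling of 24 (camera adjusted p 0.0020, and adjusted p = 0.23 with an estimated correlation) and fatty acid oxidation genes 8 of 20 (camera adjusted p 0.0022, and adjusted p = 0.28 with an estimated correlation). Xenobiotic genes gave 1 rising and 8 falling of 18, or 1 and 9 adjusted over the list alone (camera adjusted p 0.0022, and adjusted p = 0.24 with an estimated correlation). Lipid and sterol synthesis genes gave 1 and 10 of 22 (camera adjusted p 0.0027, and adjusted p = 0.19 with an estimated correlation). Of 3 lymphocyte markers 2 fell (camera adjusted p 0.0063, and adjusted p = 0.13 with an estimated correlation). Of 18 pericentral genes 11 fell and none rose (camera adjusted p 5.4e-05, and adjusted p = 0.14 with an estimated correlation). Cyp2e1, an ethanol-oxidising cytochrome, fell by 1.16 ± 0.20 (SE, n = 3 against 4), after −0.11 ± 0.18 from control to mild, which did not pass. Glul, the glutamine synthetase gene, fell by 0.73 ± 0.11, a change that ended with peaks within 10 kb of the start (−0.04). Of 16 lipid droplet genes 9 fell and 1 rose, or 10 and 1 adjusted over the list alone (camera adjusted p 0.0056, and adjusted p = 0.14 with an estimated correlation). G0s2 fell by 0.58 ± 0.13, and Plin4 fell by 0.42 ± 0.11, a call that ended without FPC_Advanced replicate 2 (−0.27). Of 15686 genes 225 rose from control to mild and fell from mild to advanced. They held 7 of the 16 lipid droplet genes, Cd36, Cidec, Fitm1, G0s2, Hilpda, Plin4 and Pparg (Fisher's exact test adjusted p 6.1e-08 over 52 tests). That test takes genes as independent, and both steps share the mild libraries, so its p does not measure the spread between mice. In edgeR 10135 peaks were higher and 10020 lower, but 11745 in all without FPC_Advanced replicate 2. Beside the Rasa2 (2.28 ± 0.19) and Mir181c (2.19 ± 0.18) peaks, a promoter peak of Cd63, a tetraspanin of endosomes (mm10 chromosome 10, 128909687 to 128909887), rose by 2.13 ± 0.17. The Dkk4 peak fell 16.0-fold, and peaks of 4930482G09Rik, Cacna2d3 and Cyp2e1 changed by −3.01, −2.98 and −2.83.

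On CDAHFD fewer peaks passed in this comparison. Of the biliary and progenitor genes 9 of 17 rose, or 14 adjusted over the list alone (camera adjusted p 3.3e-06, and adjusted p = 0.097 with an estimated correlation), and 5 of 18 pericentral genes fell, or 6 adjusted over the list alone (camera adjusted p 0.0028, and adjusted p = 0.34 with an estimated correlation). Of 15 cholangiocyte markers 7 rose and none fell, or 9 and 1 adjusted over the list alone (camera adjusted p 0.0018, and adjusted p = 0.16 with an estimated correlation). Of 15 YAP and TEAD targets 8 rose and 1 fell, or 9 and 3 adjusted over the list alone (camera adjusted p 0.014, and adjusted p = 0.18 with an estimated correlation). AP-1 genes gave 9 rising of 17, or 10 adjusted over the list alone (camera adjusted p 0.00014, and adjusted p = 0.16 with an estimated correlation). Bile acid genes gave 4 falling of 18, or 6 adjusted over the list alone (camera adjusted p 0.00078, and adjusted p = 0.26 with an estimated correlation), and xenobiotic genes 6 of 18, or 8 adjusted over the list alone (camera adjusted p 0.0021, and adjusted p = 0.33 with an estimated correlation). Hepatocyte transcription factors gave 5 falling of 18 (camera adjusted p 0.021, and adjusted p = 0.30 with an estimated correlation). Fatty acid oxidation genes gave 1 rising and 3 falling of 20, or 1 and 6 adjusted over the list alone (camera adjusted p 0.021, and adjusted p = 0.52 with an estimated correlation). Of 3 lymphocyte markers 2 fell (camera adjusted p 0.0054, and adjusted p = 0.16 with an estimated correlation). Cyp2e1 fell by 1.06 ± 0.19, after 0.35 ± 0.17 from control to mild, which did not pass but did without CDAHFD_Control replicate 2 (0.55). In edgeR 6389 peaks were higher and 4996 lower, but 6855 in all without CDAHFD_Advanced replicate 2 and 6910 with all libraries thinned to the same total. The Cd63 promoter peak rose by 1.60 ± 0.16, from 9.14 ± 1.78 CPM (SD, n = 4) to 27.8 ± 2.97 CPM (n = 3), and peaks of Mir1953, Rhoc and Mir181c by 1.58, 1.58 and 1.54. Peaks of Prex1, Dkk4, A930013F10Rik and Camk2b changed by −2.77, −2.74, −2.45 and −2.27. Male-biased genes fell on both diets in this step, 9 of 15 on FPC and 6 of 15 on CDAHFD, or 10 adjusted over the list alone (camera adjusted p 2.2e-06 and 1.8e-05, and adjusted p = 0.057 and 0.097 with an estimated correlation).

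A test of the difference between diets asks where the change from control was not the same. Several genes of fatty acid synthesis differed: Scd1, Fasn, Acaca and Pnpla3 lost accessibility on CDAHFD and not on FPC. Scd1, the stearoyl-CoA desaturase gene, was 0.32 ± 0.14 in advanced FPC livers and −0.82 ± 0.14 in advanced CDAHFD livers, a difference of 1.14 ± 0.20 (adjusted p 0.0017, edgeR). The FPC value of Scd1 did not pass without FPC_Control replicate 2 (0.34), FPC_Control replicate 3 (0.30), FPC_Advanced replicate 1 (0.21) or FPC_Advanced replicate 3 (0.28). Pnpla3, a lipid droplet hydrolase, was 0.56 ± 0.10 on FPC and −0.47 ± 0.10 on CDAHFD, a difference of 1.03 ± 0.14 (adjusted p 0.00022, edgeR), although its promoter peaks alone gave 0.09 on CDAHFD. Sqle, a sterol synthesis enzyme, went the other way, with −0.31 ± 0.08 on FPC, 0.38 ± 0.08 on CDAHFD and a difference of −0.70 ± 0.11, although its promoter peaks alone gave −0.09 on CDAHFD. Fasn, the fatty acid synthase gene, differed by 0.68 ± 0.16 and Acaca, the acetyl-CoA carboxylase gene, by 0.73 ± 0.17. Both calls ended without CDAHFD_Advanced replicate 1 (0.59 and 0.65), and that of Fasn also without FPC_Advanced replicate 1 (0.53), where Fasn fell on FPC too (−0.33). In mild livers the differences were 1.68 ± 0.18 for Scd1, 0.75 ± 0.15 for Fasn, 1.06 ± 0.16 for Acaca, 0.96 ± 0.13 for Pnpla3 and −0.98 ± 0.11 for Sqle. These 5 genes, and the choice of contrasts in which single genes are given, were singled out after their values were seen. The whole list of lipid and sterol synthesis genes had 4 higher and 4 lower of 22 in advanced livers, or 7 and 7 adjusted over the list alone, and its median of −0.14 and mean of 0.09 differed in sign (camera adjusted p 0.71).

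**Figure D5:**
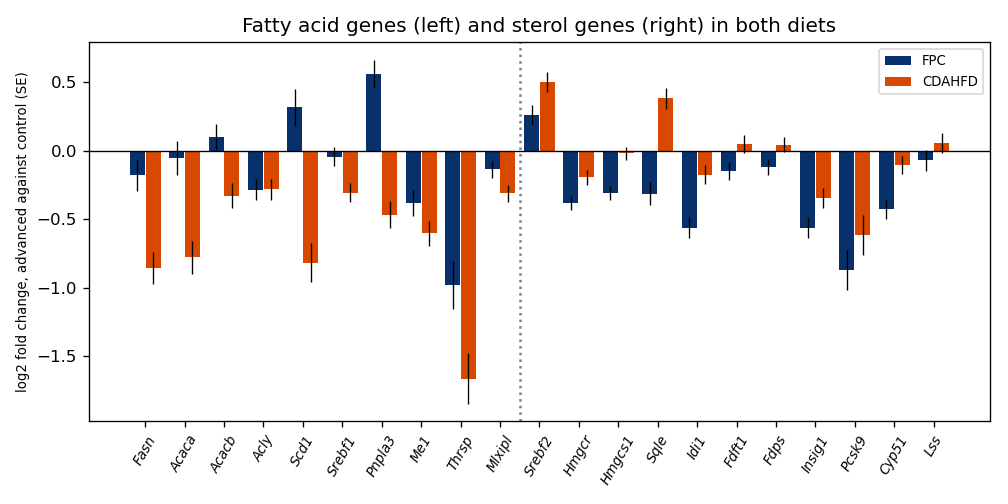
Log2 fold change of gene sums with SE, advanced against control, for 10 fatty acid genes (left of the dotted line) and 11 of the 12 measured sterol genes (right) on FPC (blue, n = 3 against 4) and CDAHFD (orange, n = 3 against 4). Scd1 is 0.32 on FPC and −0.82 on CDAHFD, and Sqle is −0.31 and 0.38.

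Camera called NRF2 targets lower on FPC relative to CDAHFD, although most members did not pass singly. Of 16 NRF2 targets 3 were lower and none higher in the advanced comparison, or 6 adjusted over the list alone (camera adjusted p 0.00072, and adjusted p = 0.11 with an estimated correlation). In the mild comparison 5 were lower, or 7 adjusted over the list alone (camera adjusted p 7.5e-05, and adjusted p = 0.091 with an estimated correlation). Gsta2, a glutathione transferase, was −0.71 ± 0.08 on FPC and 0.14 ± 0.08 on CDAHFD in advanced livers, a difference of −0.85 ± 0.12. Hspa5 differed by −0.50 ± 0.09, Mdm2 by −0.60 ± 0.10 and Klf6, an immediate early transcription factor, by −0.41 ± 0.08, while Glis2 was higher on FPC by 0.66 ± 0.10. The ER and integrated stress list had 2 lower genes of 15, or 4 adjusted over the list alone (camera adjusted p 0.018, and adjusted p = 0.11 with an estimated correlation). In the mild comparison it had 3 lower (camera adjusted p 0.099), and p53 targets 1 lower of 14 (camera adjusted p 0.18). Camera also called the inflammation list (adjusted p 0.022, and adjusted p = 0.49 with an estimated correlation), p53 targets (0.033, and adjusted p = 0.40 with an estimated correlation), and pericentral and secreted protein genes (0.022 each, and adjusted p = 0.65 with an estimated correlation) lower on FPC in advanced livers. Among named peaks, the Pnpla5 peak differed most, with 4.004 in advanced and 4.64 in mild livers. In edgeR the advanced comparison gave 475 peaks higher and 626 lower on FPC, and the mild comparison 1269 and 1122. With all libraries thinned to the same total these numbers fell to 403 and 1221 in all. The number for advanced livers fell to 582 without FPC_Advanced replicate 3, to 646 without FPC_Control replicate 3, to 655 without CDAHFD_Advanced replicate 3, to 676 without CDAHFD_Advanced replicate 1 and to 693 without CDAHFD_Control replicate 3, and the number for mild livers to 1242 without FPC_Control replicate 3. The control groups of the 2 diets, which differ in feeding time and cohort, differed at 1411 higher and 455 lower peaks, with 968 in all without FPC_Control replicate 1, 1096 without FPC_Control replicate 3, 1039 without CDAHFD_Control replicate 3 and 1144 after thinning.

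Losses lay mostly away from promoters. Of the peaks lost in advanced livers 12.6% on FPC and 13.8% on CDAHFD lay within 1 kb of a transcription start, against 32.2% and 37.0% of unchanged peaks (odds ratios 0.304 and 0.273, Fisher's exact test). Gained peaks of advanced FPC livers lay there more often (41.2%, odds ratio 1.48), and those of advanced CDAHFD livers less often (34.4%, odds ratio 0.894), which turned to 1.23 with cyclic loess scaling. The share of all counts in promoter peaks rose from 41.4% ± 0.728 (SD, n = 4) in FPC controls to 43.5% ± 0.927 (n = 4) in mild and 46.2% ± 0.486 (n = 3) in advanced livers. On CDAHFD it was 41.3% ± 0.524 (SD, n = 4), 43.6% ± 0.945 (n = 4) and 44.7% ± 1.30 (n = 3). Promoter peaks had a median log2 change of 0.22 on FPC and 0.12 on CDAHFD in advanced livers, intergenic peaks −0.13 and −0.12, and intronic peaks −0.17 and −0.14.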

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

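The tests on cell markers, secreted protein genes, sex-biased genes and thinned libraries, and the gap between ranges with separate controls, were chosen after the results were seen. Those ranges, the diet differences and leaving out libraries were planned.

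Biliary and YAP-type genes gained accessibility in advanced livers on both diets. A lower share of hepatocyte nuclei would raise the markers of every other cell type alike only if those cells kept their proportions. Whether they did was not tested. Cholangiocyte markers exceeded endothelial markers by a median of 0.932 on FPC (0.70 against −0.23) and 0.783 on CDAHFD (0.41 against −0.37), but both gaps lie within the SD of the cholangiocyte markers (1.23 and 1.32), and only that on FPC exceeds the SD of the endothelial ones (0.854 and 0.908), so a lower share stays open. Nuclei of bile duct cells carried over by the pull-down, which should remove them, stay open too: of 15 cholangiocyte markers 2 fell on FPC and 11 rose, and 1 fell on CDAHFD and 8 rose, and 11 of the 15 also stand in other lists. The marker levels were low for Krt7 (1.00 to 7.92 CPM on FPC) and high already in controls for Onecut2 (332 and 306 CPM). Hepatocytes that take up a biliary program may account for the gain, and these explanations cannot be told apart without single nuclei.

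Male-biased genes lost accessibility in advanced livers, and dilution by other nuclei would lower all hepatocyte genes by about as much, but the difference of male-biased and secreted protein genes had a median of −0.413 on FPC (−0.90 against −0.49) and −0.632 on CDAHFD (−0.91 against −0.27). The secreted protein genes, which dilution would have to lower that far, fell short by more than their SD (0.256 and 0.254) on both diets. That argues against dilution as the whole cause only if other nuclei add equally little to the sums of both lists, which was not tested. Both differences also lie within the wider SD of the male-biased genes (0.644 and 0.698), and a part in the loss stays open. A switch to the female program would raise female-biased genes by about as much, but their median was −0.0405 on FPC and −0.260 on CDAHFD. A change within hepatocytes may underlie the rest, a hypothesis found and tested on the same data, and depth, GC content and the submitters' histological grouping were not tested for it.

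Mild CDAHFD livers lay further along the advanced change than mild FPC livers. Unequal depth is argued against, since with all libraries thinned to the same total the difference was still 14.7 percentage points (48.4% against 63.2%). The shared controls are argued against as well, since with separate controls a gap of 9.24 points was left between the highest FPC value (50.7%) and the lowest CDAHFD value (59.9%). Diet, feeding time, cohort and the histological cutoff between mild and advanced remain open and were not tested, and any of them may underlie it.

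In 604 groups of 4 libraries, 29 values stood apart from the other 3 by Dixon's test at 5%, where chance alone gives about 30.2. Among library measures these were the total count of FPC_Control replicate 3 (6.04 in units of 1e6, against 3.79 to 4.17) and the share of counts in the top 100 peaks of FPC_Mild replicate 3 (0.993%, against 1.04% to 1.05%). Among named peaks they were 4930482G09Rik in FPC_Mild replicate 2 (21.2 CPM), Nfkbiz and Pard3b in FPC_Mild replicate 1 (28.1 and 8.03 CPM) and Irf5 in CDAHFD_Control replicate 2 (36.2 CPM). Among genes in FPC controls they were Bicc1 (5.08 CPM) and Cyp27a1 (165 CPM) in replicate 4, Creb3l3 (109 CPM) in replicate 3 and Cd14 (13.5 CPM) in replicate 1. In mild FPC livers they included Rxra (477 CPM) and Acaca (78.1 CPM) in replicate 1, Cyp2a4 (7.59 CPM) and Itgam (20.3 CPM) in replicate 2, Akr1d1 (178 CPM) and Mogat1 (126 CPM) in replicate 3 and Fgf21 (74.3 CPM) in replicate 4. In CDAHFD controls they were Icam1 (36.9 CPM) in replicate 1, Hao2 (33.0 CPM), Postn (2.12 CPM) and Hsd3b5 (106 CPM) in replicate 2, Insig1 (637 CPM) in replicate 3 and Myof (6.62 CPM) and Nqo1 (15.2 CPM) in replicate 4. In mild CDAHFD livers they were Slco1b2 (153 CPM), Tnfrsf10b (18.4 CPM) and G0s2 (80.2 CPM) in replicate 3 and Thrsp (130.4 CPM) in replicate 4.

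The change from control differed between the diets, FPC minus CDAHFD on the log2 scale in edgeR, for 46 named values. Peaks of advanced livers were 4930482G09Rik (−1.84), Ttc36 (−2.33), 9130401M01Rik (−1.97), Camk2b (1.40), Gm13547 (2.35), Pard3b (1.74) and Pnpla5 (4.004). Peaks of mild livers were Dkk4 (1.17), Ttc36 (−1.20), Mir181c (−2.19), 9130401M01Rik (−1.71), Gm30332 (1.39), Gm13547 (1.66), Pard3b (2.08), Trhde (0.88), Larp4b (−0.80), Cacna2d3 (1.14), Pnpla5 (4.64) and Dmbt1 (1.94). Genes of advanced livers that were higher on FPC were Ttr (0.28), Glis2 (0.66), Scd1 (1.14), Fasn (0.68), Acaca (0.73) and Pnpla3 (1.03). Those lower on FPC included Tdo2 (−0.62), Idi1 (−0.39), Klf6 (−0.41), Hspa5 (−0.50), Gsta2 (−0.85), Aox1 (−0.42), Mdm2 (−0.60), Mcm5 (−0.32), Gls2 (−0.45), Sqle (−0.70) and Hmgcs1 (−0.29). Genes of mild livers were Elovl3 (0.75), Cyp2d9 (0.73), Scd1 (1.68), Fasn (0.75), Acaca (1.06), Pnpla3 (0.96), Idi1 (−0.34), Gsta2 (−0.78) and Sqle (−0.98). Leaving out FPC_Advanced replicate 2 ended the calls of Tdo2 (−0.52) and Aox1 (−0.39) in advanced livers, and CDAHFD_Advanced replicate 1 those of Fasn (0.59), Acaca (0.65), Idi1 (−0.34) and Ttr (0.28). The call of Ttr also ended without any 1 of FPC_Control replicates 1, 2 and 3, FPC_Advanced replicates 1 and 3, CDAHFD_Control replicates 3 and 4 and CDAHFD_Advanced replicates 2 and 3 (0.24 to 0.30). That of Idi1 in advanced livers ended without FPC_Control replicate 3, FPC_Advanced replicates 1 or 3 or CDAHFD_Control replicate 3 (−0.38 to −0.35). In mild livers that of Idi1 ended without FPC_Control replicates 3 or 4, FPC_Mild replicates 2 or 3, CDAHFD_Control replicates 1 or 3 or CDAHFD_Mild replicates 2 or 3 (−0.33 to −0.30). The call of Mcm5 ended without FPC_Control replicates 1 or 3, FPC_Advanced replicates 1 or 3, CDAHFD_Control replicates 2 or 3 or CDAHFD_Advanced replicates 2 or 3 (−0.32 to −0.28). The call of Fasn in advanced livers ended without FPC_Advanced replicate 1 as well (0.53).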

How the results depend on the processing

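All 72 named peak results kept their direction and their side of the threshold in all 1496 recomputations. Direction and side were also kept in 5475 of 5698 recomputations of 377 named gene results and in 649 of 692 of 50 list results. The named peaks were picked for large changes without overlap between groups, so their stability was nearly fixed by that choice. It does not speak for other peaks. The rounding, thinning and separate promoter scaling were chosen after the data were seen. Scaling by RLE, total counts or cyclic loess left each count of called peaks within 1.5 times the reported one. Where a result below changed, the cause was not tested, except that stricter thresholds call fewer peaks by construction. Leaving out a library did not always lower the count. For the diet differences in advanced and mild livers it gave up to 1351 and 3214 peaks, against 1101 and 2391 with all libraries. With a log2 change above 1 also required, called peaks numbered 14471 for advanced against control, 5527 for mild against control and 6689 for advanced against mild on FPC, 14763, 8706 and 3517 on CDAHFD, 624 and 1542 for the diet differences in advanced and mild livers, 485 for the controls and 14079 for both diets together. At an adjusted p under 0.01 there were 11036 for mild against control and 11893 for advanced against mild on FPC, 5554 for advanced against mild on CDAHFD, 203 and 595 for the diet differences and 660 for the controls. Thinning gave 6910 for advanced against mild on CDAHFD, 403 and 1221 for the diet differences and 1144 for the controls. Leaving out each library in turn gave 32414 to 36787, 15406 to 17836 and 11745 to 19392 on FPC, with the lowest of the last without FPC_Advanced replicate 2. On CDAHFD it gave 33210 to 37184, 24427 to 27548 and 6855 to 11233, with the lowest of the last without CDAHFD_Advanced replicate 2. For the diet differences the ranges were 582 to 1351 and 1242 to 3214, for the controls 968 to 1806, for both diets 44395 to 46385 and for shared peaks 25733 to 28415. The lowest counts of the diet differences were those without FPC_Advanced replicate 3 (582) and FPC_Control replicate 3 (1242), and of the controls without FPC_Control replicate 1 (968). The graded change ranged from 45.2% to 52.0% on FPC, with 45.2% without FPC_Advanced replicate 1, and from 61.0% to 65.4% on CDAHFD, and the called lists from 10 to 11 and from 9 to 10. With an estimated correlation camera called 0 lists on either diet (7 and 4 at an unadjusted p under 0.05, and 18 and 19 by fry). The promoter odds ratio of peaks gained in mild FPC livers was 1.03 at 2.5 kb (Fisher's exact test adjusted p 0.32). Cyclic loess turned that of peaks gained in advanced against mild FPC livers to 1.53, in advanced CDAHFD livers to 1.23 and in mild CDAHFD livers to 1.05. With promoter peaks alone the sign turned for Insig1 (0.13 on FPC, 0.18 on CDAHFD), Ctsc (0.25 and 0.79), Klf6 on FPC (−0.11), Pparg in mild FPC livers (−0.0318), and on CDAHFD Tnfrsf1b (−0.0629), Mcm5 (0.0595), Cdk1 (0.25), Pnpla3 (0.0880), Sqle (−0.0943) and Hmgcs1 (0.23). With peaks within 10 kb it turned for Ctsc (0.81 and 1.27), and on CDAHFD for Cdk1 (0.30) and Pnpla3 (0.13). Limma on the deposited normalized signal changed the share of higher peaks in the mild diet difference from 53.1% to 41.5%. The alternative without a filter changes nothing, since the filter kept all peaks. Motif searches and GC offsets were not run for lack of a mm10 sequence. On simulated FPC data with few changed peaks 31.3% of 1.5-fold changes in peaks were recovered. Whether depth limits small changes in the real data was not tested.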

Other observations

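The tests of lipid genes in this part were chosen after the results were seen, and the divisions of the libraries were planned.

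Beside the lipid droplet genes, some genes of the pericentral zone were more accessible in mild FPC livers than in both control and advanced ones. Of 18 pericentral genes 4 were higher in mild livers in this way, Axin2, Nkd1, Slc1a2 and Sp5 (odds ratio 19.9, Fisher's exact test adjusted p 0.0028 over 52 tests). Here too the test takes genes as independent, and both steps share the mild libraries. On CDAHFD 46 of 15686 genes were higher in mild livers than in both other groups, against 225 on FPC, and no list held more than 1 of the 46. Genes lower in mild livers than in both other groups numbered 88 on CDAHFD and 134 on FPC. In mild FPC livers 675 peaks rose above the level of advanced livers and 326 fell below it, against 154 and 244 on CDAHFD.

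The list of lipid synthesis genes was divided by function after its values were seen, into 10 fatty acid and 12 sterol genes. In advanced livers the median difference, FPC minus CDAHFD, was 0.55 for fatty acid and −0.25 for sterol genes, 0.803 apart, with 4 fatty acid genes higher on FPC and 4 sterol genes lower. In mild livers 6 fatty acid genes were higher and 2 sterol genes lower, with medians of 0.66 and −0.17. Because the division followed the values, these numbers do not test whether the diets move the 2 kinds of genes apart. Lipid droplet genes were over-represented among the genes that were higher in mild FPC livers than in both control and advanced ones, with 7 of 16 members (Fisher's exact test adjusted p 6.1e-08). That p takes genes as independent and rests on the same mild libraries in both steps. With an estimated correlation camera called the list in neither step (adjusted p 0.40 for mild against control and 0.14 for advanced against mild). Mild and advanced livers came from different mice after the same 20 weeks of diet, so these values give no order in time.

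Other divisions of the same libraries were tested with limma-trend for each comparison. On FPC, 1 of 35 divisions, the real one, gave as many called peaks for advanced against control (35951, highest other 1), mild against control (19572, highest other 1) and advanced against mild (19385, highest other 0). The same was true of genes, with 9052, 6156 and 4616 and highest others of 0. On CDAHFD it was also 1 of 35, with 35092 peaks (highest other 419), 26024 (64) and 12680 (2901), and 8421 genes (12), 6631 (0) and 3043 (686). No other division gave as many, which argues against an accidental division of mice. Chance is not excluded, since 1 of 35 is the smallest share that 35 divisions allow. The same held for the control groups (1 of 35, 736 peaks, highest other 367). It also held for both diets together (1 of 100, 45247 peaks, highest other 24451) and shared peaks (1 of 100, 26469, highest other 0), where 1 of 100 is likewise the smallest share. For the advanced diet difference 1 of 100 divisions, the real one, gave as much, with 378 peaks (highest other 160) and 369 genes (highest other 70). For the mild diet difference 3 of 100 divisions gave as much, with 2384 peaks (highest other 3312) and 800 genes (highest other 927). The divisions for the diet differences exchanged diets within a stage. They thereby mixed the difference between cohorts, which the contrast removes, into the groups, and this could lower the other counts. These divisions therefore do not exclude chance for either diet difference.

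For the number of lists that camera calls, chance cannot be excluded. As many lists were called in 7 of 35 divisions for advanced FPC (10, highest other 11), 5 for mild FPC (7, highest other 11) and 3 for advanced against mild FPC (14, highest other 15). On CDAHFD the divisions numbered 7 (9, highest other 12), 2 (9, highest other 9) and 2 (12, highest other 12). For the diet differences they were 19 of 100 in advanced livers (6, highest other 11) and 71 of 100 in mild livers (1, highest other 9). The counts of list members that rose or fell rest on the tests of single genes and not on this number.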
